A study of Arabidopsis thaliana with 9 samples.

How the data were processed

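RNA sequencing was done by the authors on whole Arabidopsis thaliana seedlings, 7 days old and grown on plates in long days without treatment. There were 9 libraries in 3 groups of 3 biological replicates: En2 wild type, a RAV1 over-expression line and bes1-D, a gain-of-function mutant known for its stabilised BES1 protein. The promoter and the number of independent lines behind the RAV1 over-expression samples are not given in the sources used here.

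The authors deposited 1 table with a value in FPKM (fragment counts scaled to transcript length and to the mapped fragments of the library) for every library at 25199 loci. Per the labels, FastQC 0.10.1, TopHat2 and Cufflinks 2.1.1 were used with the TAIR10 genome, and any further scaling between libraries or filter on genes is not stated. Column sums ran from 890880 to 971271 FPKM and the distributions differed between libraries, so the values had not been quantile normalized. Of the loci, 25135 were matched to the TAIR10.1 gene table by identifier, 327 were at 0 in every library and 1 value was blank (AT5G19720 in bes1-D replicate 1). Fragment counts were not used here, so the absolute depth is unknown and no counting interval or detection limit is given. A relative depth was estimated from the most frequent ratio to En2 wild type replicate 1 among 1206 low loci. It put the libraries between 85% and 112% of that library. The estimate rests on few loci: 133 to 216 were compared per library, and 12 to 29 of them lay at the peak.

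Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Loci with at least 1 FPKM in at least 3 libraries were tested, which left 19740. All 9 libraries were fitted together as group means (6 residual degrees of freedom), followed by 3 contrasts with moderated statistics (trend and robust options): RAV1 over-expression against wild type, bes1-D against wild type, and RAV1 over-expression against bes1-D. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and all tests were two-sided. RAV1 and BES1 were also compared by exact permutation of 3 against 3 libraries, for which 0.1 is the smallest p possible. Error values are standard deviations (SD) of FPKM or standard errors (SE) of log2 changes. Figures were drawn with matplotlib 3.10.9, and numpy 2.4.6 and pandas 2.3.3 were used in Python 3.11.15.

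The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. There were 26 gene lists with 292 genes, of which 289 were in the table and 254 were tested. They covered the RAV family, the BES1/BZR1 family, brassinosteroid biosynthesis and signalling, cell wall loosening (expansins and xyloglucan hydrolases), PRE growth factors with IBH1, auxin response, gibberellin metabolism, cellulose synthases, photosynthesis, salicylic acid defence, jasmonate synthesis and response, jasmonate/ethylene defence, pattern-triggered immunity, camalexin and indole glucosinolates, aliphatic glucosinolates, flavonoid and anthocyanin synthesis, leaf senescence, abscisic acid response, cold response, ethylene signalling and flowering. The remaining 4 lists were markers of tissue and handling: root markers, seed maturation, circadian clock, and touch and wound early response. The gibberellin list had only 2 tested members and was not tested as a list, which left 25 list tests per comparison. Each list was tested with camera at a preset correlation between genes of 0.01, which compares the list with all other genes, with p adjusted over the 25 lists of a comparison. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. Members were counted over all genes tested and adjusted over the list alone. Lists for hypoxia response and iron deficiency response were written after the data were seen, so their p is descriptive. It was adjusted over these added lists alone.

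Named genes were RAV1, BES1 and their families, and up to 4 members of each list with the smallest p in a comparison. The rule also took the 8 largest rises and falls per comparison among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM. For genes called in opposite directions it took 5 per direction pair. Where a list had 5 or fewer called members and the rule had not taken all of them, the rest are named as chosen after their values were seen.

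The overlap of both comparisons with wild type was set beside the product expected for independent lists. It was also set beside 100 simulations of unchanged groups measured against the same wild-type libraries, because shared controls push both comparisons the same way. With 3 controls it was not possible to give each comparison its own 2 or more. Fits and list tests were checked on simulated data of 19740 genes. For changed genes of at least 5 FPKM, 92.4% of 2-fold changes were recovered in the design of the RAV1 comparison and 89.4% in that of bes1-D. Recovery of 1.5-fold changes was 70.6% and 52.9%, with 12 and 10 false calls. Both comparisons were simulated with the same layout and gene-wise spread, so these shares differ by the genes drawn and not by genotype. In the list check, camera called the salicylic acid list after a shift of 0.7 (log2), and also 1 list that was not shifted. Simulated genes were drawn independently, so this does not check camera for lists whose genes vary together.

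Alternatives, changed 1 at a time, were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, trimmed-mean scaling, replicate number as a block, fits of only the 2 groups compared, no trend and no robust option, a 2-fold minimum, an adjusted p under 0.1 for the overlap, camera with an estimated correlation, and leaving out each of the 9 libraries. Library quality weights were added after seeing the data. After the fit, the labels of 6 libraries were regrouped in all 10 ways per comparison, and all 9 libraries in 100 ways for the overlap. FPKM was also divided by the share of all transcripts outside the photosynthesis list, a test chosen after seeing the data. Replicate number was not used to pair the samples across genotypes in the main fit. Correlations of deviations lay between -0.08 and 0.15 for same-numbered libraries of different groups and between -0.16 and 0.07 for differently numbered ones. Weak pairing is therefore not excluded, and the replicate block stood as an alternative. Sequence data were not analysed here, so splicing, transgene reads and sequence variants were left out.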

Results

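Transcript levels were measured by RNA sequencing in whole 7-day-old seedlings of 3 genotypes, with 3 biological replicates each: En2 wild type, a line that over-expresses RAV1, and bes1-D, a gain-of-function mutant of BES1. The absolute depth of the libraries is unknown, since the values used here are FPKM. Relative to En2 wild type replicate 1 (100%), the estimated depth was 85% and 108% in the other wild-type libraries. It was 92%, 105% and 85% in RAV1 over-expression replicates 1 to 3, and 92%, 112% and 112% in bes1-D replicates 1 to 3. Each library had between 22241 and 22551 loci above 0 FPKM. Pearson correlations of log2(FPKM + 1) across genes lay between 0.9695 and 0.9851 within groups and between 0.9173 and 0.9747 across groups (genes are not independent replicates). The main axis of variation (54% of the variance) set the RAV1 over-expression libraries apart from the rest, and the next axis (16.1%) set bes1-D apart from wild type.

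The series title asks whether RAV1 and BES1 hold down each other's expression. RAV1 (AT1G13260, chromosome 1, 4542168 to 4543970, plus strand, TAIR10.1), a transcription factor with AP2 and B3 domains, measured 84.1 ± 13.9 FPKM in wild type, 1080 ± 335 in its over-expression line and 48.5 ± 13.4 in bes1-D (SD, n = 3 each). BES1 (AT1G19350, chromosome 1, 6688463 to 6691216, plus strand), a transcription factor of the brassinosteroid pathway, measured 108 ± 13.1 FPKM in wild type, 62.2 ± 10.6 in RAV1 over-expression and 154 ± 25.2 in bes1-D (SD, n = 3 each). RAV1 was 12.9-fold higher in its over-expression line (log2 change 3.63, SE 0.26, adjusted p = 0.000116). BES1 fell in that line, to a level 42.3% below wild type (log2 change -0.79, SE 0.15, adjusted p = 0.00508), with all 3 libraries below every wild-type library. In bes1-D the RAV1 mean was 42.4% below wild type, but the difference did not pass the test over all genes (log2 change -0.81, SE 0.26, adjusted p = 0.0929). It stayed short of the test whichever library was left out (adjusted p from 0.0549 to 0.254). The BES1 mean was 1.43-fold that of wild type in bes1-D (log2 change 0.5, adjusted p = 0.0692), also short of the test. Confidence intervals at the 0.05 level, not adjusted over other genes, each lay on 1 side of no change. They ran from -1.4 to -0.22 for RAV1 and from 0.17 to 0.84 for BES1.

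Set against each other, the lines differed in both genes: RAV1 was higher in RAV1 over-expression than in bes1-D (log2 difference 4.44, adjusted p = 1.32e-05). BES1 was lower there (-1.29, adjusted p = 0.000238). Exact permutation gave a two-sided p of 0.1 for RAV1 and for BES1 in every comparison, the smallest that 3 against 3 libraries allow. The bes1-D mutation is known to act on the stability of the protein, which these data do not measure, and FPKM does not separate reads of an introduced RAV1 copy from those of the native gene. The 3 RAV1 over-expression libraries differed in RAV1 itself, which measured 756 FPKM in replicate 2, 1064 in replicate 1 and 1426 in replicate 3.

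**Figure D1:**
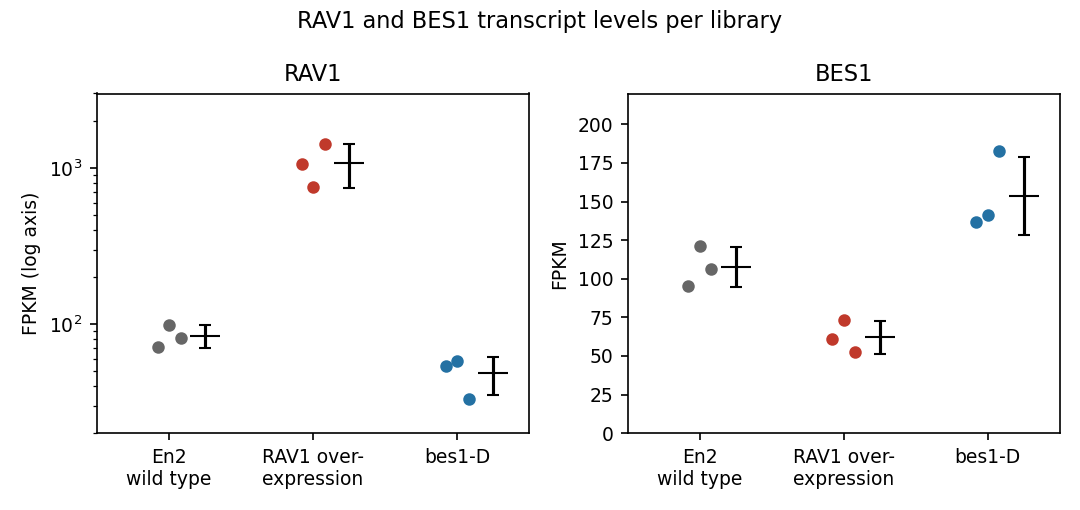
RAV1 (left, FPKM on a log axis) and BES1 (right, FPKM) in each of the 9 libraries, as points by genotype, with the mean and SD of 3 replicates as a bar. RAV1 over-expression libraries lie between 756 and 1426 FPKM for RAV1, and their BES1 values lie below every wild-type value.

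Relatives of both genes changed in RAV1 over-expression. All 3 other RAV family members that were tested fell: TEM1 (AT1G25560) from 205 to 55.1 FPKM (log2 change -1.97, adjusted p = 0.00359), RAV2/TEM2 (AT1G68840) from 168 to 43.5 (-2.01, adjusted p = 0.00338) and EDF3 (AT3G25730) from 16.3 to 7.36 (-1.05, adjusted p = 0.00287). TEM1 and TEM2 are known repressors of flowering. Of the other BES1/BZR1 family members, BEH1 (AT3G50750) fell from 14.4 to 4.92 FPKM (-1.38, adjusted p = 0.00054), and BZR1 (AT1G75080), the closest relative of BES1, rose from 21.9 to 33.8 (0.6, adjusted p = 0.00774). BEH4 was also called (0.34, adjusted p = 0.028), but not under trimmed-mean scaling or quantile normalization. Its call was lost without En2 wild type replicates 1 or 3 or any RAV1 over-expression library (adjusted p from 0.0554 to 0.0986). In bes1-D the called members were EDF3, at 7.93 FPKM (-0.99, adjusted p = 0.00967), and BEH2. BEH2 (AT4G36780) fell from 37 to 13.9 FPKM (-1.35, adjusted p = 1.43e-05). Neither family passed camera as a list in RAV1 over-expression (adjusted p = 0.125 and 0.446) or in bes1-D (0.0822 and 0.801). Adjusted over the list alone, 2 RAV family members were lower in bes1-D, and of the BES1/BZR1 family 1 was higher and 2 lower.

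The comparison of RAV1 over-expression with wild type asks what the line changed. Photosynthesis transcripts fell: all 20 members of the list were lower, with a median log2 change of -1 (camera adjusted p = 5.75e-15; adjusted p = 0.465 with an estimated correlation). All 20 passed when adjusted over the list alone. LHCB1.3 (AT1G29930), a light-harvesting protein of photosystem II, fell from 10900 to 5090 FPKM (log2 change -1.14, adjusted p = 0.00186). LHCA2 (AT3G61470), of the photosystem I antenna, fell from 2280 to 1110 FPKM (-1.07, adjusted p = 0.00179), and GLK1 (AT2G20570), a transcription factor of chloroplast development, from 26.4 to 8.54 (-1.5, adjusted p = 0.00179). The 20 genes together took 8.24% ± 0.27 of all FPKM in wild type and 4.84% ± 0.99 in RAV1 over-expression (SD, n = 3 each), with 5.86% in replicate 2, 4.77% in replicate 1 and 3.88% in replicate 3. Under quantile normalization 9 of the 20 passed, and LHCB1.3 did not (log2 change 0), since that setting gives the most abundant genes of every library the same values.

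Aliphatic glucosinolate genes, which make methionine-derived defence compounds, also fell in RAV1 over-expression: 10 of 11 members were lower, with a median log2 change of -0.95 (camera adjusted p = 8e-10; adjusted p = 0.465 with an estimated correlation). The count was 10 when adjusted over the list alone. CYP79F1 (AT1G16410), an entry enzyme of the pathway, fell from 68.4 to 23.9 FPKM (-1.47, adjusted p = 0.000336). SOT17 (AT1G18590), a sulfotransferase of its last steps, fell from 70.5 to 29.6 (-1.25, adjusted p = 0.00105), and MYB28 (AT5G61420), its main transcription factor, from 63.2 to 35.6 (-0.81, adjusted p = 0.000914). Among 18 cell wall loosening genes 5 fell and 1 rose, with a median of -0.4 (camera adjusted p = 0.000776; adjusted p = 0.465 with an estimated correlation). Adjusted over the list alone, 7 fell and 1 rose. XTH33 (AT1G10550) fell from 17.2 to 5.47 FPKM (-1.49, adjusted p = 0.000661) and EXPA5 (AT3G29030), an expansin, from 5.08 to 2.02 (-1.03, adjusted p = 0.0101). EXPA1 also fell, as did EXPA8 and XTH17, which are named after their values were seen. XTH24 (AT4G30270) rose from 227 to 437 FPKM (0.95, adjusted p = 0.0103). The number of lower members was 2 without En2 wild type replicate 2 or replicate 3, 3 without RAV1 over-expression replicate 3 and 8 without its replicate 2. EXPA1 lost its call without En2 wild type replicates 2 (adjusted p = 0.0607) or 3 (0.0509).

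Salicylic acid defence genes rose in RAV1 over-expression, with 7 of 13 members higher and a median log2 change of 0.59 (camera adjusted p = 0.0201; adjusted p = 0.465 with an estimated correlation). The count was 8 when adjusted over the list alone. SARD1 (AT1G73805), a transcription factor of salicylic acid synthesis, rose from 1.19 to 9 FPKM (2.05, adjusted p = 0.00266). SAG101 (AT5G14930) rose from 16.2 to 30.3 FPKM (0.88, adjusted p = 0.0019) and PAD4 (AT3G52430) from 10.6 to 16.5 (0.59, adjusted p = 0.0101); both are partners of EDS1 in defence signalling. Ethylene signalling genes rose as well, with 6 of 9 higher and a median of 0.41 (camera adjusted p = 0.0201; adjusted p = 0.465 with an estimated correlation). There were 8 when adjusted over the list alone. Several of them are known to restrain the pathway. The receptor ETR2 (AT3G23150) rose from 23.7 to 84.7 FPKM (1.85, adjusted p = 0.000813) and the kinase CTR1 (AT5G03730) from 38.7 to 62.6 (0.68, adjusted p = 0.00626). The F-box genes EBF1 and EBF2, the latter named after its value was seen, rose from 71.2 to 95.2 and from 97.8 to 135. EIN3, which activates the pathway, also rose. Without 1 library, the salicylic acid count was 4 (without En2 wild type replicate 1), 3 (without its replicate 2), 4 of 11 (without RAV1 over-expression replicate 1) and 3 of 12 (without its replicate 3). The ethylene count was 2, 2, 3 and 3 without the same libraries. Under trimmed-mean scaling 2 ethylene genes passed and under quantile normalization 3. The salicylic acid list was not called with a filter of 5 FPKM (adjusted p = 0.194). EBF1 lost its call without En2 wild type replicates 1 or 2 or RAV1 over-expression replicate 1 (adjusted p from 0.0654 to 0.0878), and EIN3 without En2 wild type replicates 1 or 2 or RAV1 over-expression replicate 3 (from 0.0655 to 0.106).

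Seed maturation genes stood far above wild type in RAV1 over-expression, a fact to read beside the other changes of this line. Of the tested members 6 of 8 rose, with a median log2 change of 3.05 (camera adjusted p = 0.000776; adjusted p = 0.517 with an estimated correlation). All 8 passed adjusted over the list alone. CRC (AT4G28520), a cruciferin seed storage protein, went from 3.37 ± 1.76 FPKM to 337 ± 370 (SD, n = 3; log2 change 5.65, adjusted p = 0.00427). It measured 58.2 in replicate 2, 196 in replicate 1 and 757 in replicate 3. EM1 (AT3G51810) and EM6 (AT2G40170), late embryogenesis proteins, rose from 0.0367 to 13.6 FPKM (3.29, adjusted p = 0.00609) and from 1.03 to 25.7 (3.22, adjusted p = 0.00914). The count was 2 of 7 without RAV1 over-expression replicate 1 and 3 of 8 without En2 wild type replicate 2. Abscisic acid response genes included RAB18 (AT5G66400), a dehydrin, which rose from 2.05 to 41.7 FPKM (3.46, adjusted p = 0.00418). RD29A (AT5G52310) rose from 7.22 to 28 (1.79, adjusted p = 0.00115) and the transcription factor ABI5 (AT2G36270) from 0.72 to 4.86 (1.71, adjusted p = 0.00304). HAI1 (AT5G59220) and RD29B, the latter named after its value was seen, brought that count to 5 of 10, and the list was not called by camera (adjusted p = 0.17).

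**Figure D2:**
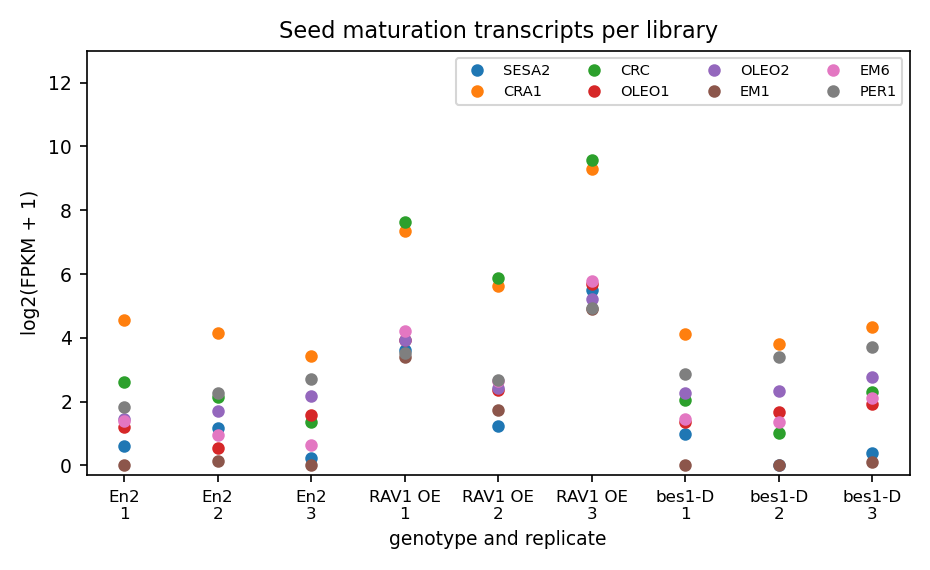
The 8 tested seed maturation genes in each of the 9 libraries, as log2(FPKM + 1), 1 point per gene and library. Every RAV1 over-expression library lies above the wild-type libraries for CRC, which reached 58.2, 196 and 757 FPKM there.

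Other hormone and stress genes moved in RAV1 over-expression without a call for their list. In the jasmonate list 7 of 17 members rose and 2 fell (camera adjusted p = 0.516). Without En2 wild type replicates 1, 2 and 3, 3, 4 and 4 rose and 1 fell, without RAV1 over-expression replicate 1, 3 and 1, and without its replicate 3, 7 and 1. LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, rose from 230 to 818 FPKM (1.82, adjusted p = 0.000321). VSP1 (AT5G24780), a jasmonate-induced storage protein, fell from 7.16 to 0.467 (-2.36, adjusted p = 0.00115), as did VSP2. Of the pattern-triggered immunity genes 6 of 17 rose (adjusted p = 0.259; 3 without En2 wild type replicates 1 or 2 or RAV1 over-expression replicate 1, and 3 with 1 lower under either scaling), among them the receptor kinase FRK1 (AT2G19190), from 2.03 to 14.1 FPKM (2.27, adjusted p = 0.000411). Of the leaf senescence genes 6 of 11 rose (adjusted p = 0.125; 3 without En2 wild type replicates 1 or 2, and 2 of 10 without RAV1 over-expression replicates 1 or 3), among them the chlorophyll breakdown genes NYE1 (AT4G22920; 1.13, adjusted p = 0.00441) and PPH (AT5G13800; 0.82, adjusted p = 0.00472). In the auxin list GH3.3 (AT2G23170; 2.44, adjusted p = 0.000658) and GH3.5 (AT4G27260; 0.92, adjusted p = 0.000655) rose and GH3.17 (AT1G28130) fell (-0.53, adjusted p = 0.0121) among 15 members (adjusted p = 0.426).

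Camera called neither brassinosteroid list in RAV1 over-expression. Of 10 biosynthesis genes 1 was lower (camera adjusted p = 0.248, fry adjusted p = 0.0514), and of 10 signalling genes 4 were higher and 1 lower (0.23 by camera, but 0.0255 by fry). The higher signalling genes were the receptors BRL3 (AT3G13380; 0.85, adjusted p = 0.0044) and BRI1, the co-receptor BAK1 (AT4G33430; 0.52, adjusted p = 0.00229) and the kinase BSK1 (AT4G35230; 0.59, adjusted p = 0.00964). BKI1, an inhibitor of BRI1, was the lower member and is named after its value was seen. BRI1 was not called under trimmed-mean scaling or quantile normalization, nor without any 1 of the wild-type libraries or RAV1 over-expression replicates 1 and 3 (adjusted p from 0.0532 to 0.0775). The biosynthesis gene was BR6OX1, at 1.33 FPKM in wild type and 0.52 in RAV1 over-expression. Its call was lost without any RAV1 over-expression library or bes1-D replicate 2 (adjusted p from 0.0507 to 0.118), and without any 1 wild-type library it fell below the filter and was not tested.

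The remaining lists of this comparison were not called by camera. Fry called 8 of the 25 lists here: brassinosteroid signalling, abscisic acid response (adjusted p = 0.0135), cold response (0.02) and those called by camera except cell wall loosening (0.0617). Of 8 camalexin and indole glucosinolate genes the regulator MYB51 was higher and CYP79B2 and SUR1 lower (camera adjusted p = 0.259). Of 8 flavonoid genes CHI was higher and DFR lower (0.516), and of 5 jasmonate/ethylene defence genes the chitinase PR3 was higher and the regulator ORA59 lower (0.516). CBF3 and KIN2 were the higher members among 5 cold response genes (0.101), PRE2 among 6 PRE growth factors (0.736), and SOC1, which promotes flowering, was the lower member among 4 flowering genes (0.528). Of 9 circadian clock genes TOC1, ELF4, LUX and PRR5 were higher and PRR9 lower (0.516), with 1 higher without En2 wild type replicate 2 or RAV1 over-expression replicates 1 or 3 and 2 without the other wild-type libraries. Of 14 root markers EXPA7, SCR and SHR were higher and the nutrient transporters PHT1;1 and NRT2.1 lower (0.929). PRR5 and SHR are named after their values were seen. The calls of PRE2 (adjusted p up to 0.164), SOC1 (0.123), LUX (0.126), ELF4 (0.073), CBF3 (0.0907), SCR (0.0884), PR3 (0.0819), MYB51 (0.0759) and NRT2.1 (0.0542) were each lost without at least 1 library. No cellulose synthase (of 6, adjusted p = 0.259) and no touch and wound gene (of 8, adjusted p = 0.248) was called by limma; 2 of these 14 genes had an unadjusted p under 0.05, and fry called neither list. Median, mean and camera direction differed in sign for flavonoid synthesis, flowering and root markers. Of the gibberellin genes GA3OX1 had a log2 change of -0.56 (adjusted p = 0.113) and GA20OX2 of -0.46 (adjusted p = 0.154).

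The largest rises in RAV1 over-expression included AT1G68250, listed at 0 in every wild-type library and at 219, 68.9 and 871 FPKM in RAV1 over-expression replicates 1 to 3, and CRC. They also included the seed vicilin PAP85 (AT3G22640), from 0.263 to 42.2 FPKM (4.77, adjusted p = 0.000443), the defensin LCR67 (AT1G75830), from 3.12 to 140 (4.94, adjusted p = 0.00614), and the transcription factor LBD40 (AT1G67100), from 2.12 to 74 (4.53, adjusted p = 0.000113). The others were AT3G59930, AT1G03106 and AT5G33355, with log2 changes from 5.11 to 5.42. AT5G50562 was listed at 0 in all 6 libraries of both lines and measured 69.4 FPKM in wild type. Other large falls were CIB1 (AT4G34530), a blue-light transcription factor, from 16.8 to 1.07 FPKM (-3.46, adjusted p = 0.00191), and the cytochrome P450 CYP81D11 (AT3G28740), from 25.6 to 1.27 (-3.35, adjusted p = 0.00286). They also included AT1G73600, from 368 to 41.8 (-3.67, adjusted p = 0.0115), with AT5G62360 (-3.16), AT3G62040 (-3.1) and AT1G65490 (-2.69). The plastid ribosomal gene PSRP6 was called lower (-2.88, adjusted p = 0.0453), a call lost without En2 wild type replicates 1 or 2, any RAV1 over-expression library, or bes1-D replicates 1 or 2 (adjusted p from 0.0614 to 0.159).

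In all, 2960 genes were higher and 1581 lower in RAV1 over-expression than in wild type among 19740 tested, so that 65.2% of the called genes were higher; 625 and 454 of them changed at least 2-fold. The share that was higher was 45.6% under trimmed-mean scaling (1870 higher, 2228 lower) and 47.6% under quantile normalization (1944 and 2144). The number of higher genes was 1632 without RAV1 over-expression replicate 1, 1741 without its replicate 3 and 1715 without En2 wild type replicate 2. The number of lower genes was 985 without En2 wild type replicate 2 and 1012 without RAV1 over-expression replicate 1. Among called genes, 53.8% (2441 of 4541) were ranked across the RAV1 over-expression libraries as RAV1 and CRC were, with the smallest change in replicate 2 and the largest in replicate 3. That order is 1 of 6, or 16.7%, and it was seen in 24.2% of the 6125 genes with an adjusted p of at least 0.5. Genes are not independent replicates, and these shares rest on 1 ordering of 3 libraries. The ordering was taken from these data, so the shares are descriptive. For replicates 2, 1 and 3, the log2 shift estimated for trimmed-mean scaling rose likewise (0.084, 0.104 and 0.119). Their estimated depth fell in that order (105%, 92% and 85%). Any factor shared by many genes could give such an order, and its cause was not tested.

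The comparison of bes1-D with wild type asks what the gain of BES1 function changed. Brassinosteroid biosynthesis genes fell: 6 of 10 were lower, with a median log2 change of -0.92 (camera adjusted p = 2.15e-07). This call held with an estimated correlation (adjusted p = 0.0239). Adjusted over the list alone, 6 passed. BR6OX2 (AT3G30180), which makes brassinolide, fell from 16.2 to 3.41 FPKM (-1.96, adjusted p = 4.85e-06), and CYP90D1 (AT3G13730) from 9.19 to 0.913 (-2.41, adjusted p = 2.58e-05). CPD (AT5G05690) fell from 70.1 to 20.4 (-1.74, adjusted p = 2.58e-05) and DWF4 (AT3G50660), the rate-limiting enzyme, from 9.84 to 2.52 (-1.63, adjusted p = 0.000225). The other genes of the list that fell were ROT3 and BR6OX1, named after their values were seen. In RAV1 over-expression BR6OX2 measured 14.2 FPKM, CYP90D1 9.2, CPD 56.4 and DWF4 9.45.

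Genes of indole glucosinolates, flavonoids and aliphatic glucosinolates were also lower in bes1-D. Of 8 camalexin and indole glucosinolate genes 4 fell, with a median of -0.5 (camera adjusted p = 0.00267; adjusted p = 0.321 with an estimated correlation) and 4 when adjusted over the list alone. CYP79B2 (AT4G39950) fell from 54.7 to 20.6 FPKM (-1.38, adjusted p = 0.00691), as did CYP79B3 (AT2G22330; -0.81, adjusted p = 0.00655). CYP83B1 (AT4G31500) fell from 89.1 to 51.4 (-0.78, adjusted p = 0.00268), and so did SUR1, whose call was lost without En2 wild type replicate 2 (adjusted p = 0.0581). These enzymes turn tryptophan into indole glucosinolates. Of 8 flavonoid genes 4 fell, with a median of -0.63 (camera adjusted p = 0.0045; adjusted p = 0.39 with an estimated correlation; adjusted p = 0.0574 with no filter on low values). There were 5 when adjusted over the list alone. FLS1 (AT5G08640), of flavonol synthesis, fell from 45.6 to 21 FPKM (-1.11, adjusted p = 0.00727) and CHI (AT3G55120) from 47.2 to 27 (-0.78, adjusted p = 0.00691). Their regulator MYB12 (AT2G47460) fell from 3.55 to 1.44 (-0.91, adjusted p = 0.0083), as did chalcone synthase CHS, whose call was lost without En2 wild type replicate 2 (adjusted p = 0.0512). Of 11 aliphatic glucosinolate genes 5 fell, with a median of -0.47 (camera adjusted p = 0.00164; adjusted p = 0.623 with an estimated correlation), and 7 passed adjusted over the list alone. SOT17 fell from 70.5 to 34.9 FPKM (-0.99, adjusted p = 0.00781). MYB29, CYP79F2, MAM3 and BCAT4, the last named after its value was seen, were the others. MYB29 lost its call without bes1-D replicates 2 or 3 (adjusted p up to 0.0674), CYP79F2 without any library except RAV1 over-expression replicates 2 and 3 (up to 0.122), and MAM3 without any wild-type or bes1-D library (up to 0.0886). Without any 1 wild-type library MYB29 fell below the filter and was not tested. The list had 1 lower member without En2 wild type replicates 1 or 2 or bes1-D replicate 2, 2 without En2 wild type replicate 3 or bes1-D replicates 1 or 3, and 3 without RAV1 over-expression replicate 1. It had 2 under trimmed-mean scaling and 3 under quantile normalization.

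Root markers were lower in bes1-D, a fact to read beside the other groups. Among them 5 of 14 fell, with a median of -0.54 (camera adjusted p = 0.000342; adjusted p = 0.321 with an estimated correlation), and 7 passed adjusted over the list alone. The root hair expansin EXPA7 (AT1G12560) fell from 10.3 to 3.42 FPKM (-1.35, adjusted p = 0.00226) and COBL9 (AT5G49270), a root hair gene, from 5.29 to 2.11 (-1.04, adjusted p = 0.0132), the latter without a call when En2 wild type replicate 2 was left out (adjusted p = 0.0559). PRP3 (adjusted p up to 0.105 without 1 library), the phosphate transporter PHT1;1 (up to 0.103) and the aquaporin TIP2;3, the last named after its value was seen, were the others. The count was 2 without En2 wild type replicates 1 or 2, RAV1 over-expression replicate 1 or bes1-D replicates 2 or 3, and 3 without En2 wild type replicate 3.

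Growth and stress lists showed few called genes in bes1-D. Of 18 cell wall loosening genes XTH4 was higher, at 577 against 363 FPKM (0.66, adjusted p = 0.0345), and XTH5 (AT5G13870; 18.4 to 6.37, -1.41, adjusted p = 0.00229) and EXPA10 (AT1G26770; 16.6 to 8.53, -0.89, adjusted p = 0.0138) were lower. The list was called upward with a median of 0.3 (camera adjusted p = 0.00707; adjusted p = 0.623 with an estimated correlation). Adjusted over the list alone, 5 were higher and 2 lower. XTH4 lost its call without any wild-type library, RAV1 over-expression replicate 1 or bes1-D replicates 1 or 3 (adjusted p from 0.0589 to 0.12), and EXPA10 without En2 wild type replicate 3 (0.0504). Without RAV1 over-expression replicates 2 or 3 or bes1-D replicate 2, 3 members of the list were higher. Of 10 abscisic acid genes RD22 (AT5G25610; log2 change 0.52, adjusted p = 0.0177) and COR47 (AT1G20440; 191 to 264, 0.47, adjusted p = 0.0121) were higher, with a list median of 0.33 (camera adjusted p = 0.00312; adjusted p = 0.39 with an estimated correlation) and 2 adjusted over the list alone. RD22 lost its call without any wild-type library or bes1-D replicate 2 (adjusted p from 0.0526 to 0.0698), and COR47 without En2 wild type replicate 2 (0.0586).

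**Figure D3:**
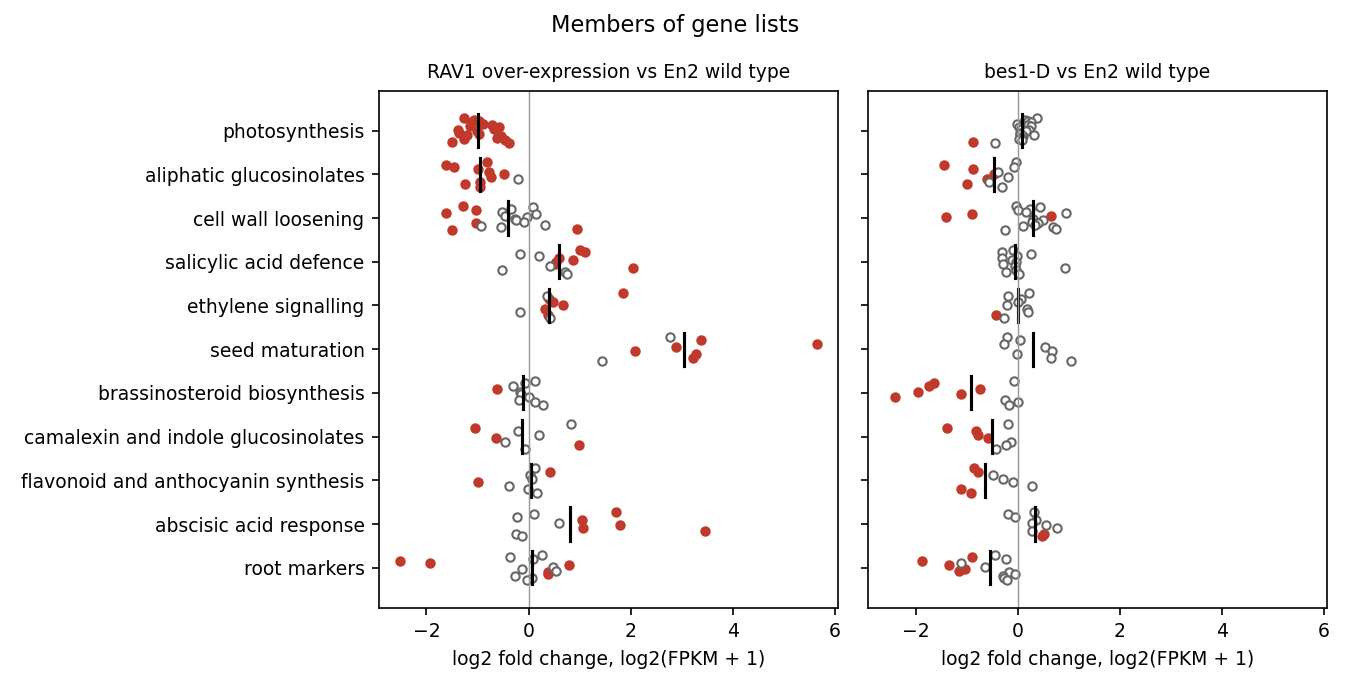
Log2 fold changes of the tested members of 11 gene lists in RAV1 over-expression (left) and bes1-D (right) against wild type, on the scale of log2(FPKM + 1). Filled points passed the test, open points did not, and bars mark medians: -1 for photosynthesis in RAV1 over-expression and -0.92 for brassinosteroid biosynthesis in bes1-D.

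The other lists of bes1-D were not called by camera. Fry called 5 of the 25 lists here: the BES1/BZR1 family (adjusted p = 0.0127) and those called by camera except cell wall loosening (0.531), abscisic acid response (0.0811) and aliphatic glucosinolates (0.0811). In the photosynthesis list the median was 0.09 (0.17 under trimmed-mean scaling and -0.03 under quantile normalization; adjusted p = 0.109), and the list took 9.11% ± 0.23 of all FPKM (SD, n = 3). Its called member was GLK1 (log2 change -0.88, adjusted p = 0.0411), lost under both scalings and without any wild-type library, RAV1 over-expression replicates 1 or 2, or bes1-D replicates 2 or 3 (adjusted p from 0.0505 to 0.125). Of 17 jasmonate genes LOX2 fell (log2 change -1.15, adjusted p = 0.00648), the regulator MYC2 was lower and the synthesis genes AOC1 and AOC2 were higher (camera adjusted p = 0.225). Of 15 auxin response genes SAUR22 and SAUR15 were higher (0.0756), and of 11 leaf senescence genes the sugar transporter SWEET15 (AT5G13170), from 4.03 to 13.9 FPKM (1.56, adjusted p = 0.00691; camera 0.0756). BIM1, a partner of BES1, was the lower member of 10 brassinosteroid signalling genes (0.801). The ethylene signalling list was not called (0.801). Of 17 pattern-triggered immunity genes RBOHD was higher and the receptor EFR lower (0.801), and of 9 circadian clock genes PRR7 was higher (0.292). Without at least 1 library the calls were lost of MYC2 (adjusted p up to 0.126), AOC1 (0.0931), AOC2 (0.076), SAUR22 (0.0556), SAUR15 (0.0656), BIM1 (0.0585), RBOHD (0.154), EFR (0.107) and PRR7 (0.136). Limma called no gene in the lists of PRE growth factors (0.919), cellulose synthases (0.801), salicylic acid defence (0.801), jasmonate/ethylene defence (0.919), cold response (0.801), flowering (0.345), seed maturation (0.211) and touch and wound response (0.345). Of the 55 genes in these 8 lists, 12 had an unadjusted p under 0.05, and fry called 0 of the lists for 1 direction and 2 for mixed change. Median, mean and camera direction differed in sign for 9 of the lists not called: brassinosteroid signalling, PRE growth factors, cellulose synthases, salicylic acid defence, jasmonate/ethylene defence, leaf senescence, cold response, ethylene signalling and the circadian clock.

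The largest rises in bes1-D were 2 pseudogene loci near background in the other genotypes, AT2G12040, at 19.8 ± 1.13 FPKM (SD, n = 3; 0.0433 in wild type), and AT1G36400, at 16.9 ± 2.81 (0.0967 in wild type). NEET (AT5G51720), an iron-sulfur protein of chloroplasts, rose from 23.8 to 107 FPKM (2.18, adjusted p = 0.00144) and GRP20 (AT5G07560) from 1.28 to 8.77 (2.18, adjusted p = 0.00325). AT3G42723 (2.82), AT3G24542 (2.39) and AT3G54730 (2.24) were the others, besides AT5G33355 (3.72, adjusted p = 0.0455), which lost its call without any wild-type library, RAV1 over-expression replicates 1 or 2, or bes1-D replicates 1 or 2 (adjusted p from 0.0666 to 0.15). The falls were AT5G50562, AT2G30766, from 46.1 to 1.32 FPKM (-4.35, adjusted p = 6.16e-06), AT5G05250 (-3.32), AT5G57785 (-3.07), AT1G57720, from 269 to 31.9 (-3.04, adjusted p = 1.08e-07), AT3G20790 (-2.67) and the root arabinogalactan gene AGP30 (AT2G33790), from 115 to 16.9 (-2.79, adjusted p = 0.000501). AT5G57567 was called as well (-2.66, adjusted p = 0.0414), but not without En2 wild type replicates 1 or 3, RAV1 over-expression replicate 1, or bes1-D replicates 1 or 2 (adjusted p from 0.065 to 0.132).

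In all, 433 genes were higher and 1139 lower in bes1-D than in wild type, so that 27.5% of the called genes were higher; 88 and 206 changed at least 2-fold. The share that was higher was 47.3% under trimmed-mean scaling (631 higher, 703 lower) and 41.8% under quantile normalization (588 and 820). The higher genes numbered 193, 160 and 219 without En2 wild type replicates 1, 2 and 3, 279 without RAV1 over-expression replicate 1 and 234 without bes1-D replicate 2. The lower genes numbered 531, 456, 581, 750 and 606 without the same libraries.

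RAV1 over-expression and bes1-D were also compared with each other, which tests the difference between the lines itself. Brassinosteroid biosynthesis genes were higher in RAV1 over-expression than in bes1-D, with 6 of 10 past the test and a median log2 difference of 0.71 (camera adjusted p = 0.00316; adjusted p = 0.274 with an estimated correlation); 6 passed adjusted over the list alone. BR6OX2 differed by 1.79 (adjusted p = 5.72e-06), CYP90D1 by 2.42 (adjusted p = 1.1e-05) and CPD by 1.43 (adjusted p = 3.18e-05). Cell wall loosening genes were lower in RAV1 over-expression, with 13 of 18 lower and 2 higher and a median of -0.71 (camera adjusted p = 2.76e-06; adjusted p = 0.428 with an estimated correlation); adjusted over the list alone, 14 were lower and 2 higher. XTH4 measured 265 against 577 FPKM (-1.13, adjusted p = 0.000686) and XTH33 5.47 against 14.6 (-1.24, adjusted p = 0.000704), while XTH5 (1.38, adjusted p = 0.00045) and EXPA10 (1.05, adjusted p = 0.00154) were the higher members. Photosynthesis genes were lower in RAV1 over-expression, 19 of 20 with a median of -1.1 (camera adjusted p = 9.49e-15; adjusted p = 0.428 with an estimated correlation) and 19 adjusted over the list alone; under quantile normalization 10 passed. Aliphatic glucosinolate genes differed as a list, with 5 of 11 lower and a median of -0.38 (camera adjusted p = 0.000963; adjusted p = 0.597 with an estimated correlation); 5 were lower and 1 higher adjusted over the list alone. CYP79F1 (-1.39, adjusted p = 0.000182) and MYB28 (-0.79, adjusted p = 0.000503) were among the lower genes, with SOT18, MAM1 and CYP83A1, and MAM3 was higher; CYP83A1 and MAM3 are named after their values were seen.

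Defence genes went both ways between the lines. Of 13 salicylic acid genes 8 were higher in RAV1 over-expression and ICS1 lower (camera adjusted p = 0.113), and of 17 jasmonate genes 7 were higher and AOS and VSP1 lower (0.445). Of 5 jasmonate/ethylene defence genes ERF1 was higher and ORA59 and PR4 lower (0.437). Of 17 pattern-triggered immunity genes 7 were higher (0.353), against 4 higher and 1 lower under either scaling. Of 15 auxin genes GH3.3, GH3.5 and IAA2 were higher and 6 lower (0.11), or 3 lower without RAV1 over-expression replicate 1 or bes1-D replicate 3. ICS1, AOS, VSP1 and IAA2 are named after their values were seen. Calls were lost without 1 library for PR4 (adjusted p up to 0.132), ORA59 (up to 0.0796) and ICS1 (without RAV1 over-expression replicates 2 or 3 or bes1-D replicate 1), and 1 jasmonate gene was lower without bes1-D replicate 2. Called genes included LOX2 (2.97, adjusted p = 1.1e-05), FRK1 (3.13, adjusted p = 3.56e-05), SAG101 (1, adjusted p = 0.000522) and PAD4 (0.9, adjusted p = 0.000747), all higher in RAV1 over-expression. The auxin-induced growth genes SAUR22 (AT5G18050; -2.51, adjusted p = 0.00145) and SAUR15 (AT4G38850; -1.74, adjusted p = 0.00191) were lower there. IBH1 (AT2G43060), a known repressor of cell elongation, was higher (0.95, adjusted p = 0.00376). Among the largest differences, the early light-induced gene ELIP2 (AT4G14690) measured 205 FPKM in RAV1 over-expression and 9.7 in bes1-D (4.21, adjusted p = 3.11e-05), OPR1 (AT1G76680) 32.3 and 374 (-3.43, adjusted p = 0.000314), and the light-harvesting gene LHB1B1 (AT2G34430) 188 and 1820 (-3.39, adjusted p = 0.000178). The other 21 lists were not called by camera, with seed maturation nearest to the threshold (6 of 8 higher, adjusted p = 0.0571; 2 of 7 without RAV1 over-expression replicate 1 and 3 without bes1-D replicate 2). Among them, 8 of 14 root markers were higher in RAV1 over-expression (median 0.49; camera adjusted p = 0.11, from 0.0054 to 0.597 over the alternatives). Fry called 14 of the 25 lists here, root markers included (adjusted p = 0.00231), but not aliphatic glucosinolates (0.075). Limma called no cellulose synthase and no flowering gene between the lines; 3 of these 10 genes had an unadjusted p under 0.05. Median, mean and camera direction differed in sign for the RAV family, PRE growth factors, jasmonate/ethylene defence, abscisic acid response, the circadian clock and touch and wound response.

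In all, 5520 genes were higher and 2084 lower in RAV1 over-expression than in bes1-D (72.6% higher), of which 984 and 643 differed at least 2-fold. Trimmed-mean scaling moved the median log2 difference of all genes by -0.173, and quantile normalization by -0.157. Under them the share that was higher was 43.4% (2392 higher, 3114 lower) and 47.9% (2714 and 2953). Without RAV1 over-expression replicate 1 the number of higher genes was 3534.

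The series title also asks whether RAV1 and BES1 act on growth and defence genes in opposite directions. Genes called in both comparisons with wild type numbered 447: 189 changed in opposite directions and 258 in the same direction, against 205.5 and 156.2 for independent lists of these sizes. Genes higher in RAV1 over-expression and lower in bes1-D numbered 120 (170.8 for independent lists), and 67 (66.6) under trimmed-mean scaling and 76 (80.8) under quantile normalization. The 5 with the largest changes in both were ELIP2 (3 and -1.2), UPI (AT5G43580; 2.71 and -1.48), a proteinase inhibitor of defence, the peptide growth factor gene PSK2 (AT2G22860; 1.76 and -1.63), AT4G15700 (1.44 and -1.22) and AT2G14247 (1.37 and -1.66). Genes lower in RAV1 over-expression and higher in bes1-D numbered 69 (34.7 for independent lists), led by the sugar transporter SWEET10 (AT5G50790; -2.02 and 1.41), AT1G53690 (-1.78 and 1.26), AT5G38100 (-1.75 and 1.37), AT4G04293 (-1.32 and 1.19) and AT5G53820 (-1.08 and 1.29). They numbered 127 (71.2) under trimmed-mean scaling and 109 (63.9) under quantile normalization, so which of these classes was larger depended on the scaling. All 189 also passed the direct comparison of the lines. Opposite changes add up in that comparison, so this is no separate evidence for them. Of these 10 genes, PSK2 and AT2G14247 kept both calls without any 1 library. The bes1-D calls of the other 8 were lost without at least 1 (adjusted p from 0.0514 for AT4G15700 without bes1-D replicate 3 to 0.139 for SWEET10 without En2 wild type replicate 2). AT5G53820 also lost its RAV1 call (adjusted p up to 0.102, without RAV1 over-expression replicate 1).

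LOX2 and EXPA7 stood out among the list genes called in opposite directions: LOX2 had log2 changes of 1.82 in RAV1 over-expression and -1.15 in bes1-D, and EXPA7 measured 10.3 FPKM in wild type, 18.9 in RAV1 over-expression and 3.42 in bes1-D. CHI measured 47.2, 63.6 and 27 FPKM. CHI lost its RAV1 call under both scalings and without En2 wild type replicates 2 or 3 or RAV1 over-expression replicates 1 or 3 (adjusted p from 0.062 to 0.12). CYP79B2, SOT17, SUR1, MYB29 and EDF3 were among the genes lower in both lines.

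Across all tested genes the log2 changes of both comparisons had a Pearson r of 0.136, a Spearman rho of 0.133 and a covariance of 0.0261 (genes are not independent replicates). Unchanged groups simulated against the same wild-type libraries gave a median r of 0.451 and a rho of 0.389 from the shared controls alone. Their median covariance was 0.0181, and a median of 0 genes was called in either pattern. The simulated groups held no true changes, which widen the spread of log2 changes, so their r and rho are not comparable with the observed ones. The lower observed r is therefore no sign of opposite changes. The observed covariance, which is not divided by that spread, lay above the simulated interval (0.0163 to 0.0212). The controls could not be divided between the comparisons, so part of the 258 genes in the same direction may come from the shared wild-type libraries. Under trimmed-mean scaling 194 genes were opposite and 304 in the same direction, against 137.8 and 139.1 for independent lists. Under quantile normalization 185 and 313 were seen, against 144.6 and 147. Opposite genes thus lay below the number for independent lists without scaling and above it under both scalings. Same-direction genes lay above it in every case. With unscaled values, the opposite genes numbered 81, 72 and 77 without En2 wild type replicates 1, 2 and 3. They numbered 90 without RAV1 over-expression replicate 1 and 124 without bes1-D replicate 2. Those in the same direction numbered 113, 87, 161, 131 and 146.

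**Figure D4:**
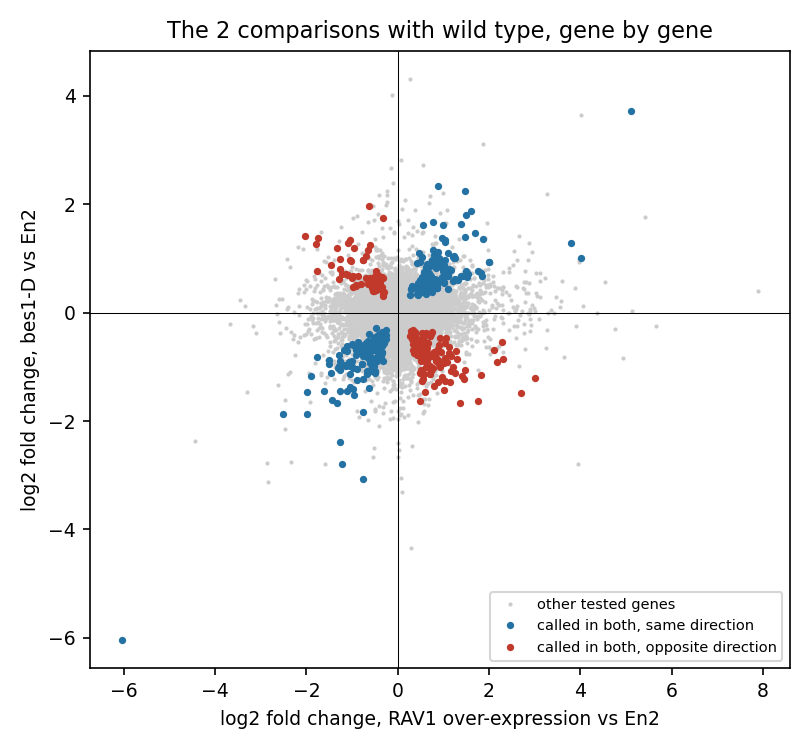
Log2 fold changes of 19740 genes in RAV1 over-expression (x axis) and bes1-D (y axis) against wild type, on the scale of log2(FPKM + 1). Coloured points are the genes called in both comparisons, 189 in opposite and 258 in the same direction.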

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

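All tests in this part were chosen before the data were examined, except the fits with library quality weights, which were chosen after seeing the data. RAV1 in its over-expression line and BES1 in that line kept their direction and their side of the threshold under every alternative run, with log2 changes without 1 library from 3.41 to 3.87 for RAV1 and adjusted p from 0.00235 to 0.0248 for BES1. RAV1 in bes1-D did not pass under any alternative run, and BES1 in bes1-D passed with library quality weights alone (log2 change 0.41, adjusted p = 0.0264; without 1 library from 0.0506 to 0.207). Of 260 calls of named genes, 191 held under every alternative in which the gene was tested, 69 were lost under at least 1 and 0 reversed. Of 111 uncalled ones, 52 were gained. Some genes fell below the filter under an alternative and were not tested there. Of 17 list calls, brassinosteroid biosynthesis in bes1-D held throughout and 16 were lost, each with an estimated correlation, while 15 of 58 uncalled lists were gained under at least 1 alternative. That setting left 0 gene lists and 0 tissue lists in RAV1 over-expression, 1 and 0 in bes1-D, and 0 gene lists in the direct comparison. With the preset correlation the counts were 5, 6 and 4 gene lists and 1, 1 and 0 tissue lists.

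Scaling changed the split of directions. Trimmed-mean scaling gave 1870 genes higher in RAV1 over-expression, 703 lower in bes1-D and 2392 higher in the direct comparison; quantile normalization gave 1944 and 2714 for the first and last of these. Both set 2 tissue lists past the test in the direct comparison. That count was 1 with a pseudocount of 0.1, no filter on low values, a filter of 5 FPKM, or the replicate block. In the fit with a replicate block, 2804 genes were higher and 1550 lower in RAV1 over-expression, and 360 and 927 in bes1-D. Fits of 2 groups gave 10 gene lists and 2 tissue lists in bes1-D. The correlation r across genes was 0.191 with a pseudocount of 0.1 (covariance 0.0666), 0.179 with no filter and 0.0921 with a filter of 5 FPKM (rho 0.105, covariance 0.0168). The cause was not tested.

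With a 2-fold minimum, which is stricter by construction, 625 genes were higher and 454 lower in RAV1 over-expression, 88 and 206 in bes1-D, and 984 and 643 in the direct comparison, with 19 in opposite directions and 34 in the same. An adjusted p under 0.1 gave 401 opposite and 551 same. Library quality weights gave 6182 higher and 3168 lower in RAV1 over-expression, 1137 and 2684 in bes1-D, 8789 and 3291 in the direct comparison, and 791 opposite and 1076 same.

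Without 1 library, genes higher ran from 1632 to 3393 and lower from 985 to 1812 in RAV1 over-expression, from 160 to 501 and from 456 to 1216 in bes1-D, and from 3534 to 5289 higher and 1627 to 2183 lower in the direct comparison. Opposite genes ran from 72 to 216 and same-direction genes from 87 to 307. The r ran from 0.114 to 0.208, rho from 0.103 to 0.198 and covariance from 0.0224 to 0.0434. Gene lists ran from 5 to 7, 6 to 10 and 4 to 5, and tissue lists from 1 to 2, 1 to 2 and 0 to 1. The absolute depth is unknown, so what it limits could not be given. On simulated data 70.6% and 52.9% of 1.5-fold changes were recovered in the RAV1 and bes1-D comparisons, so smaller changes may be missed. Both used the same layout and spread, so the gap between them comes from the genes drawn. Far fewer genes were changed there than were called in the data, so recovery in the data may differ.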

Other observations

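The lists for hypoxia and iron deficiency, both tests on seed maturation genes and the levels outside the photosynthesis list were chosen after the result was seen; the other tests of this part were chosen before. Genes of the hypoxia response were higher in RAV1 over-expression, 11 of 13 with a median log2 change of 1.3 (camera adjusted p = 9.33e-07; adjusted p = 0.301 with an estimated correlation). ADH1, an alcohol dehydrogenase of fermentation, rose from 19.2 to 157 FPKM (3.03, adjusted p = 0.00125), PDC1, the step before it, from 20.1 to 145, and the sucrose synthase SUS4 from 2.07 to 17.8. In bes1-D limma called 0 of the 13 (median 0.22, camera adjusted p = 0.0567).

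Genes of the iron deficiency response were lower in bes1-D, 6 of 12 with a median log2 change of -1.06 (camera adjusted p = 8.43e-07; adjusted p = 0.0923 with an estimated correlation). The transcription factor BHLH101 fell from 2.95 to 0.107 FPKM, the regulator PYE from 24.9 to 9.29, the transporter OPT3 from 106 to 53.3 and BTS, a ubiquitin ligase of the iron response, from 31.4 to 14.4. In RAV1 over-expression NAS4, which makes the metal carrier nicotianamine, was the 1 lower member (-1.71, adjusted p = 0.00505).

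Seed maturation genes such as CRC were higher in RAV1 over-expression, and replicate 3 held the highest level. Without that library the median log2 change of the tested members was 2.03, which argues against replicate 3 alone. Of 12 members, 8 had every RAV1 over-expression library above every wild-type library, while SESA1, SESA3, SESA4 and PER1 did not. By chance 0.6 would be expected in that direction (10% of genes in either). The members vary together, with an estimated correlation of 0.88 between the tested ones. The 8 are therefore not separate observations, and their number beside 0.6 does not measure the strength of the evidence. Taken against CRC in the same library, the rise above wild type was 57.5 to 80.6% for CRA1, 0.456 to 0.736% for CRB, and -0.632 to 1.51% for SESA1, SESA3 and SESA4. Ungerminated or late-germinating seeds in the harvest may bring such transcripts, as may an effect of RAV1 on abscisic acid responses; no measured seed profile was at hand to compare these ratios with, so these cannot be told apart.

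More genes were higher than lower in RAV1 over-expression, and fewer in bes1-D. FPKM is relative, and photosynthesis genes took a smaller share of it in RAV1 over-expression and a larger one in bes1-D. Under trimmed-mean scaling 45.6% of called genes were higher in RAV1 over-expression and 47.3% in bes1-D, but this scaling centres the changes (medians -0.006 and 0.011), so it decides nothing. With levels as a share of the transcripts outside the list, 30.3% were higher in bes1-D (23.2 to 33.3% without 1 library), which argues against that share alone, and 56.4% in RAV1 over-expression (52 to 57.5%), which leaves it open there. Other effects of scale and a true change in total RNA per cell stay open.

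Pseudogene loci made up 21 of 433 genes higher in bes1-D (4.85%) and 0 of 1139 lower ones by limma, against 0.92% of tested genes (Fisher's exact p = 1.22e-12). Of the 21, 17 had a wild-type mean under 1 FPKM, where a fall could hardly be called, so these counts do not exclude noise at low levels. In RAV1 over-expression they made up 33 of 2960 higher genes (1.11%), near their share of tested genes, and 6 of 1581 lower ones (0.38%; Fisher's exact p = 0.0105). The 21 became 9, 11 and 10 without bes1-D replicates 1, 2 and 3 and 13 without En2 wild type replicate 2, and the 0 became 3 without En2 wild type replicate 3 and 1 without bes1-D replicate 1 or 3 (exact p at most 7.89e-05; 5 against 0 and exact p = 0.00153 with a filter of 5 FPKM). Noise, reads shared between near-identical copies, low levels in the shared wild-type libraries, a difference in background and an effect of genotype stay open.

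Genes at background in 1 genotype and above 5 FPKM in every library of another numbered 9. Their median was 42.2 FPKM in the group with the highest mean, and the selection itself held it above 5. Some also varied within a genotype. AT3G49551 measured 332.64, 0 and 0 FPKM in the wild-type libraries, and AT1G62886 measured 0, 44.97 and 0 in bes1-D. The 9 genes formed 0 pairs within 200 kb (permutation p = 1). Random sets of tested genes had a median of 0 pairs as well, so the test could not speak against linked segments of another accession.

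Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. The real split, the 1 as large in each case, gave 2960 higher and 1581 lower genes in RAV1 over-expression, 433 and 1139 in bes1-D, and 5520 and 2084 in the direct comparison. Since a split and its mirror are 1, the others were read by the larger of both directions, at most 1, 5 and 1 genes. For lists called by camera at the preset correlation, the real values were 6, 7 and 4 and the highest others 8, 7 and 8. With the real split counted, 5, 2 and 7 splits were as large. The number of lists called therefore did not set the real split apart from mixed ones in any comparison. Of 100 groupings of the 9 libraries, 1, the real one, gave 189 opposite genes (highest other 0). Groups of mixed genotype call few genes, so this bears on the calls alone and not on a chance overlap of the lists. Independent lists would give 205.5 opposite genes without scaling, more than were seen. Under trimmed-mean scaling 194 were seen against 137.8, and under quantile normalization 185 against 144.6. Whether opposite genes exceeded chance overlap therefore depended on the scaling. In the same direction 3 gave 258 or more; the other 2 gave 2770 and 2724, with the RAV1 over-expression libraries as controls, which points to the structure of the samples.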
